A study of Arabidopsis thaliana with 4 samples.

How the data were processed

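Whole seedlings of the α2-COP-3 mutant and of Col-0, grown side by side on a plate of agar medium with 16 h of light at 22 °C for 4 days, gave total RNA that was amplified and labelled from 0.5 µg per sample. Each of 4 Agilent arrays (design Agilent-021169) held the RNA of both genotypes from 1 biological replicate, with the dyes exchanged on 2 of them. The ratio within an array is thus already paired by plate, and the genotypes form 1 comparison with n = 4.

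Per the file headers, the scanner files were written by Feature Extraction 9.5.1.1 and hold, for each spot, the mean signal and the median local background of both channels as intensity without background subtraction. The deposited processed signals are an intensity too, after background subtraction, spatial detrending and dye normalization by that program. The deposited log ratio is the log10 of red over green processed signal. The deposited value table of the series follows that log ratio on the log2 scale, turned to Col-0 over mutant on every array, with a correlation that rounds to 0.9999 on each array. It has 31036 values per array with medians of 0.01, 0.00, -0.00 and 0.01 on replicates 1 to 4, and the rule by which the other spots were emptied is not stated.

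All values were recomputed from mean signal and median background with limma 3.58.1 in R 4.3.3. Background was corrected with normexp (offset 50), and log2 ratios were normalized within each array by loess, with a weight of 0 for control spots. Control spots and spots marked as outliers (7 to 17 per array) were left out, saturated spots were kept, and repeated spots of a probe were averaged. The arrays hold 43803 spots other than controls, for 43603 probes. Of these, 34285 were named by their accession through the reference table (assembly TAIR10.1), 1124 by the locus and 225 by the symbol in the name column. Another 1065 matched, through the name column, a locus that already had a probe named by accession, and were left out of the gene fit. The remaining 6904 probes have no locus and were left out as well, a decision taken after the data were seen. For 15 probes accession and name pointed to different loci, and the accession was used.

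For each of 26481 genes the probe with the highest mean intensity was taken. A gene was tested when that probe was well above background on all 4 arrays in at least 1 genotype, which left 20019 genes. Of 5823 genes with several measured probes, 34 had probes more than 1 log2 unit apart, and 5 (RPL18AA, GH9C2, AT1G68490, CXIP4 and PEX13) had probes called in opposite directions. In the files of replicates 2 and 4 the columns that mark spots well above background are exchanged between the channels. There, 120 and 369 spots are marked well above background in a channel where the same file does not find them positive and significant, and 0 after exchange, while replicates 1 and 3 have 0 as named and 138 and 63 after exchange. These columns were exchanged back for replicates 2 and 4, a choice made after the data were seen.

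The limma fit held a dye effect as intercept and the genotype, with moderated tests (eBayes, two-sided) and Benjamini-Hochberg adjusted p under 0.05 as the threshold. A gene not well above background in a genotype on any array has only a bound. This bound is on the mean over the arrays, carries no error, and single arrays can lie below it. For some genes it equals the plain difference of the mean levels. It was computed per channel after loess and Aquantile, as the mean of the brighter genotype against the mean, per array, of the higher of the gene's own level and the lowest level of a probe well above background. On simulated data with the spread of these arrays, the fit was tested for its power and its false calls. It called 38% of genes with a true log2 ratio of 0.5, 98% at 1, and 11 of 19799 unchanged genes. The simulation changed 200 genes and a list of 20, with noise drawn independently. It therefore does not cover data in which 32.0% of genes change or in which genes are correlated. Estimates came out low: true log2 ratios of 1 and 3 gave medians of 0.873 and 2.78. The fold sizes given here may be shrunk in the same way.

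The model, 28 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the 28 lists), with camera with an estimated correlation, and with fry, which asks only whether a list moves one way. The lists held 427 entries by locus, of which 377 carry the same symbol in the reference, and 230 entries by gene description. Another 16 entries, 15 peroxidases of other classes and the receptor kinase RLK902, were left out under the fixed rule that the reference must not contradict an entry, but were noticed after values had been seen. Named genes are the 12 largest rises and 12 largest falls among genes past the threshold with the same sign on all arrays, up to 4 called genes of each list by smallest adjusted p, and α2-COP, α1-COP, SEC31A and SEC31B. Others are marked as named after their values were seen.

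Signal over background sets the depth of an array. The median net signal on replicates 1 to 4 was 369, 473, 522 and 578.5 in green and 122, 120.5, 114 and 57 in red. All 4 arrays were on 1 slide, so that a slide effect could not be fitted. Alternatives were other background corrections, normalizations, filters, probe rules and variance models, the deposited value table, array weights, and each array left out in turn.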

Results

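RNA of whole 4-day-old seedlings of the Arabidopsis mutant α2-COP-3 and of the wild type Col-0 was compared on 4 arrays with 2 dyes, 1 biological replicate of each genotype per array (n = 4). The comparison asks which transcripts differ when α2-COP is disturbed, a subunit of the COPI coat of vesicles that bud from the Golgi. The mutant carried Cy3 on replicates 1 and 3 and Cy5 on replicates 2 and 4. Median signal over background was 369 to 578.5 in the green channel and 114 to 122 in the red channel of replicates 1 to 3, against 57 in that of replicate 4. Between 66.2% and 72.3% of spots were well above background in each channel. The number of arrays limits the precision. All ratios below are log2 of mutant over Col-0, the opposite direction to the deposited value table, with the standard error of the limma fit. Because the dye effect is fitted, that error leaves out differences between the dye orders.

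In the mutant, the signal at the brightest probe of α2-COP itself (AT2G21390) fell by 3.39 (SE 0.09, n = 4, adjusted p = 0.000281), a 10.5-fold decrease present on each of the 4 arrays. The 2 dimmer probes of the gene gave 0.05 and -0.01. SEC31A (AT1G18830), which encodes an outer subunit of the COPII coat of vesicles leaving the endoplasmic reticulum, rose by 3.27 (SE 0.28, n = 4, adjusted p = 0.00147), and by 2.80 to 6.64 in the alternative settings that tested it. Genes of jasmonate synthesis and response, of protein folding in the endoplasmic reticulum and of the SNAREs between endoplasmic reticulum and Golgi were higher in the mutant as groups (camera adjusted p = 2.47e-06 to 0.00181). Heat shock, flavonoid, ER body, iron deficiency, cell cycle, root tissue and cytosolic ribosomal protein genes were lower as groups (camera adjusted p = 3.30e-08 to 0.00315). None of these group calls holds with an estimated correlation between genes, where the lowest adjusted p was 0.560. That correlation was estimated at 0.94 for jasmonate, 0.49 for heat shock, 0.38 for flavonoid and 0.18 for ribosomal protein genes. The preset was 0.01. For cell cycle, endoplasmic reticulum folding and SNARE genes the estimate was 0.065 to 0.095. Correlation between genes is not the only reason for the lost calls. Its estimate was negative for ER body, iron deficiency and root tissue genes (-0.17, -0.036 and -0.032), and their calls were lost too.

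Of 20019 genes tested, 6413 (32.0%) changed at an adjusted p under 0.05, 3531 of them higher and 2882 lower in the mutant. By at least 2-fold, 412 genes rose and 175 fell, 587 in all, against 1297 with Agilent's processed signals, 1303 with its log ratio and 1306 with the deposited value table. The ratio had the same sign on all 4 arrays for 6101 of the 6413. The count depended on single arrays and on the normalization: it was 914 without replicate 1, 9968 without replicate 2, 939 without replicate 3 and 8121 without replicate 4. Each fit without 1 array takes its spread from the 1 pair of arrays that still share a dye order. With median centring in place of loess the count was 876, of which 752 were higher and 124 lower. There the median ratio of all genes moved from 0.01 to 0.15.

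**Figure D1:**
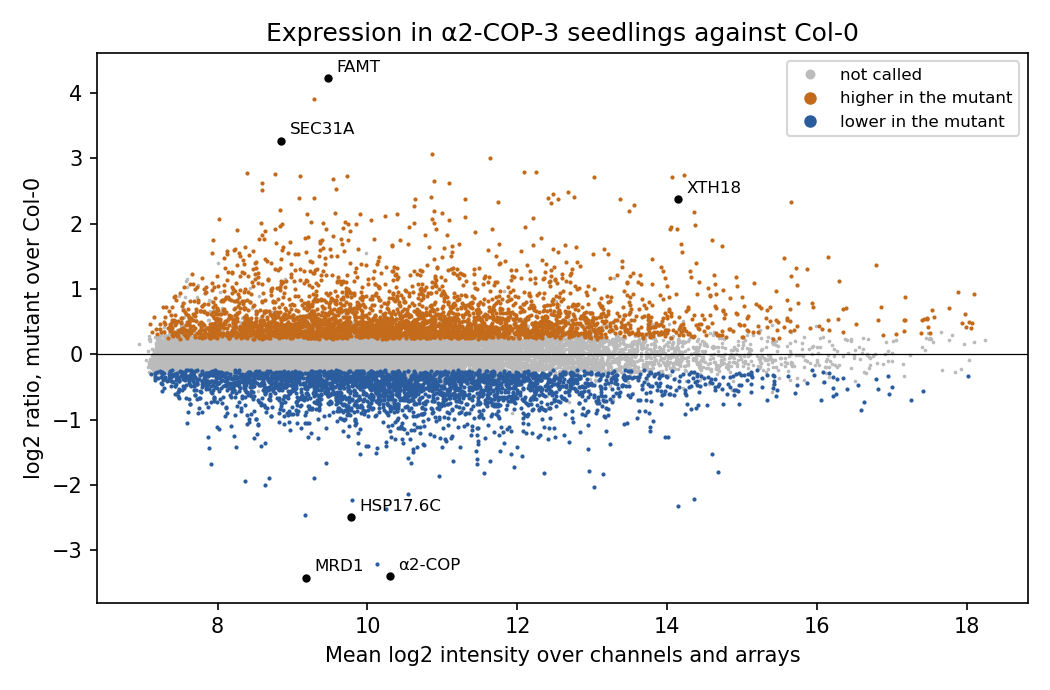
Log2 ratio of mutant over Col-0 (fitted over 4 arrays) against mean log2 intensity for each of the 20019 genes tested. Orange points are the 3531 genes higher in the mutant, blue points the 2882 genes lower, grey points did not pass, and black points are 6 named genes.

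The probe behind the α2-COP value lies at 9156382 to 9156441 on chromosome 2 (build ath1:Jan2004 of the file headers), and its ratios were -3.83, -3.04, -3.52 and -3.18 on replicates 1 to 4. The other 2 probes of the gene, both dimmer, gave 0.05 (SE 0.09) at 9152412 to 9152471 and -0.01 (SE 0.10) at 9154037 to 9154096. The first of these was well above background on 2 mutant and 3 Col-0 arrays, so that its ratio is partly one of background. The mean of the 3 probes was -1.12 (adjusted p = 0.00102). The labels do not place the mutation, so these values show a lower signal at the brightest probe and not the level of the whole transcript. Its paralogue α1-COP (AT1G62020) had a ratio of 0.00 (SE 0.09, n = 4, adjusted p = 0.977), with a different sign in 5 of the alternative settings. Of 14 measured COPI genes, 0 rose, 1 fell (α2-COP) and 13 did not pass, with the same counts adjusted over the list alone (median -0.01, camera adjusted p = 0.578).

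For SEC31A the ratios were 3.43, 2.202, 3.36 and 4.09 on replicates 1 to 4. Its Col-0 signal was well above background on 1 of the 4 arrays, which leaves the size of the ratio uncertain. It passed in all 16 alternative settings that tested it. It was not tested where genes had to be above background in both genotypes, nor with the background flags as named in the files. The other SEC31 gene, SEC31B (AT3G63460), had a ratio of -0.28 (SE 0.15, adjusted p = 0.212), 0.00 with median centring, and -0.48 without replicate 2, where it passed (adjusted p = 0.00401). Cross-hybridisation between the 2 genes was not tested. Of 22 measured COPII genes, 5 rose, 1 fell and 16 did not pass, and the counts were the same adjusted over the list alone. The risers were SEC31A, SAR1D (0.34, SE 0.08), STL2P (0.31, SE 0.07), SEC23G (0.31, SE 0.09) and SEC23C (0.26, SE 0.07), the last 2 named after their values were seen, and SEC24C fell (-0.37, SE 0.09). SAR1D did not pass in 6 of 18 alternative settings, STL2P in 7 and SEC24C in 5. STL2P and SEC24C followed the dyes, with 0.12 and -0.04 on replicate 1 and 0.06 and -0.24 on replicate 3. They had 0.58 and -0.44 on replicate 2 and 0.48 and -0.76 on replicate 4. With the deposited value table SAR1D and STL2P did not pass (adjusted p = 0.0502 and 0.0820). The list's median was -0.06 and its mean 0.11, camera gave a lower and fry a higher direction, and neither passed (adjusted p = 0.937 and 0.554). Of 12 measured ARF1 GTPases and regulators, which recruit the COPI coat, ARFA1D (0.82, SE 0.08) and ARF1A1C (0.45, SE 0.09) rose, ARFA1E (-0.67, SE 0.18) fell and 9 did not pass. These counts were the same adjusted over the list alone (median 0.05, camera adjusted p = 0.713). The fall of ARFA1E was -1.75 on replicate 4 and -0.60 to -0.06 on the others, and did not pass in 8 of 17 alternative settings, among them without the dye term (adjusted p = 0.0831) and with the deposited value table (adjusted p = 0.0543).

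**Figure D2:**
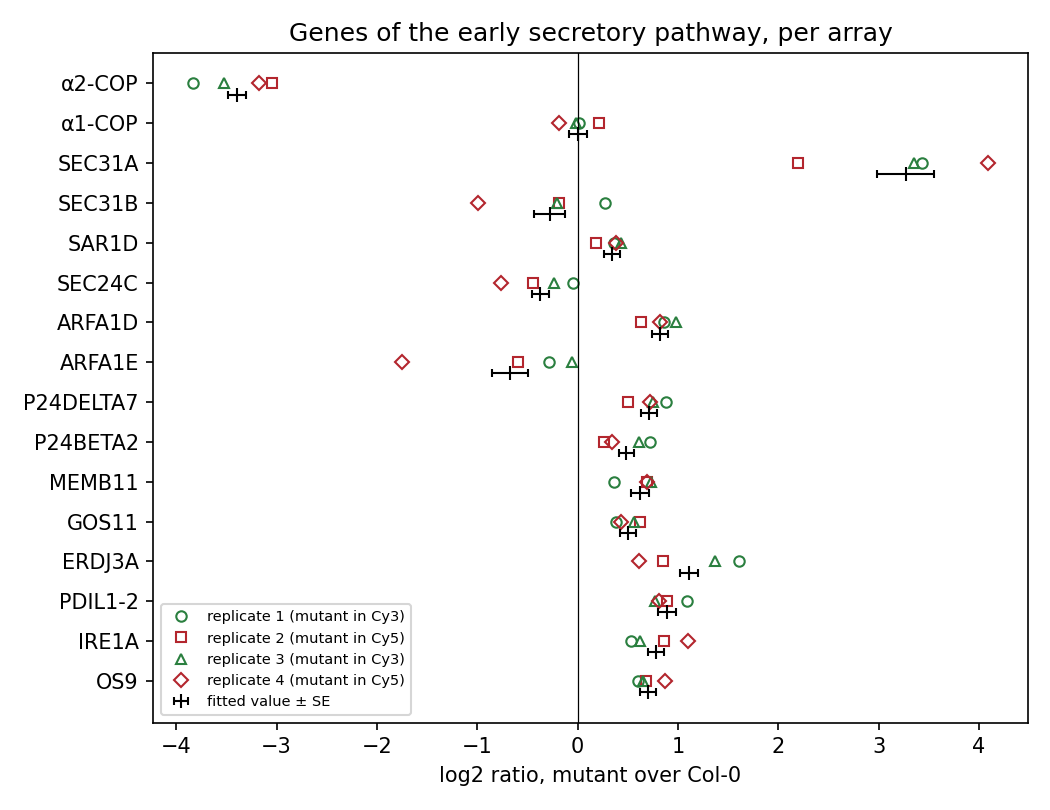
Log2 ratio of mutant over Col-0 on each of the 4 arrays (open symbols, green where the mutant carried Cy3 and red where it carried Cy5) and the fitted value with its standard error (black bars) for 16 genes of the early secretory pathway. SEC31A lies between 2.202 and 4.09 and α2-COP between -3.83 and -3.04, while α1-COP and SEC31B have arrays on both sides of 0.

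Genes of endoplasmic reticulum stress and folding were higher in the mutant: 21 of 33 rose, 1 fell and 11 did not pass, or 25 and 2 adjusted over the list alone (median 0.38, camera adjusted p = 2.47e-06, adjusted p = 0.560 with an estimated correlation). Among them were the cochaperone ERDJ3A (1.11, SE 0.09, n = 4), the disulfide isomerase PDIL1-2 (0.89, SE 0.09), the stress sensor IRE1A (0.78, SE 0.08) and OS9 (0.70, SE 0.08), a lectin of the degradation pathway for misfolded proteins. The size of the rise of ERDJ3A followed the dyes, with 1.61 and 1.37 on replicates 1 and 3 against 0.86 and 0.61 on replicates 2 and 4. BIP3, an inducible luminal chaperone, was not well above background in Col-0 on any array. It was on average at least 2.94-fold higher in the mutant (adjusted p = 0.00701), where the limit equals the plain difference of the mean levels and carries no error. BZIP17, a transcription factor of the same stress response, fell (-0.39, SE 0.10). Both were named after their values were seen. SNAREs and tethers between endoplasmic reticulum and Golgi were also higher, with 8 of 16 rising, 0 falling and 8 not passing, the same adjusted over the list alone (median 0.29, camera adjusted p = 0.00181, adjusted p = 0.560 with an estimated correlation). They include MEMB11 (0.62, SE 0.09), GOS11 (0.50, SE 0.08), SYP81 (0.41, SE 0.07) and SYP32 (0.39, SE 0.08). Of 10 measured p24 proteins and K/HDEL receptors, cargo adaptors of these vesicles, P24DELTA7 (0.71, SE 0.08), p24beta2 (0.49, SE 0.07) and p24delta5 (0.44, SE 0.08) rose, 0 fell and 7 did not pass, the same adjusted over the list alone. That list had a median of 0.20 (camera adjusted p = 0.0587, fry adjusted p = 0.0310, adjusted p = 0.587 with an estimated correlation).

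Among the 12 largest rises with the same sign on every array, FAMT (AT3G44860), a farnesoic acid methyltransferase, rose by 4.23 (SE 0.66, n = 4, adjusted p = 0.00733), and the tyrosine aminotransferase TAT3 by 3.91 (SE 0.53, adjusted p = 0.00502). On replicate 4 their ratios were 7.04 and 6.73, and on the other arrays 2.72 to 4.37 and 2.78 to 3.07. The Col-0 signal of TAT3 was well above background on 1 of the 4 arrays and that of FAMT on 3. In the alternative settings TAT3 had 2.54 to 7.03 and FAMT 2.61 to 6.80. Without replicate 1 neither passed (adjusted p = 0.0665 and 0.0508). The others are SEC31A, the chitinase family gene AT2G43620 (3.07, SE 0.23), AT3G62550 (3.01, SE 0.08), the blue copper protein BCB (2.79, SE 0.20), the xyloglucan endotransglucosylase XTR6 (2.79, SE 0.21), CORI3 (2.76, SE 0.48), the glycine-rich protein GRP5 (2.75, SE 0.11), ORS1 (2.73, SE 0.14), the defensin PDF1.4 (2.73, SE 0.25) and AT3G44870. AT3G44870, beside FAMT on the chromosome, was not well above background in Col-0 on any array. It was on average at least 6.60-fold higher in the mutant (adjusted p = 0.0261), a limit that rests in part on replicate 4. The ratios of AT3G44870 and CORI3 were 5.77 and 5.15 on that array and 1.33 to 2.66 and 1.56 to 2.38 on the others. Without it they were 1.67 and 1.97. AT3G44870 did not pass without replicate 1 (adjusted p = 0.153) or without replicate 3 (adjusted p = 0.103), nor did CORI3 (adjusted p = 0.0819 and 0.0612). With trend and robust eBayes AT3G44870 did not pass either (adjusted p = 0.0636). Cross-hybridisation between FAMT and AT3G44870 was not tested, so their values are not separate evidence.

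The 12 largest falls were led by MRD1 (AT1G53480, -3.42, SE 0.19, n = 4, adjusted p = 0.000624) and AT2G15020 (-3.40, SE 0.16), followed by α2-COP and the cysteine protease family gene AT2G27420 (-3.21, SE 0.20). The small heat shock protein gene HSP17.6C fell by 2.49 (SE 0.11), and HSP70 (AT3G12580) by 2.03 (SE 0.16). ELIP1, an early light-induced protein of chloroplasts, fell by 2.31 (SE 0.15), and VTC2, an enzyme of ascorbate synthesis, by 2.21 (SE 0.19). The remaining genes were AT2G30766 (-2.46, SE 0.08), AT5G42760 (-2.36, SE 0.17), AT1G60590 (-2.23, SE 0.20) and AT1G23205 (-2.14, SE 0.16).

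Jasmonate and wound genes were higher in the mutant: 10 of 16 rose, 0 fell and 6 did not pass, or 13 and 0 adjusted over the list alone (median 1.35, camera adjusted p = 8.47e-05, adjusted p = 0.701 with an estimated correlation). Enzymes of jasmonate synthesis were among them, AOC2 (2.14, SE 0.15, n = 4), LOX2 (2.29, SE 0.28) and AOC1 (2.38, SE 0.35), and the repressor JAZ10 (1.74, SE 0.23). AOC1 did not pass without replicate 1 (adjusted p = 0.0606). The list's median was 1.25, 1.04, 0.37 and 2.60 on replicates 1 to 4. Without replicate 4 it was 0.96 and still passed (camera adjusted p = 1.42e-05). Over all 4 arrays fry did not call the list (adjusted p = 0.164). Of 15 measured salicylic acid and pathogen genes, 5 rose, 1 fell and 9 did not pass, the same adjusted over the list alone (median 0.44, camera adjusted p = 0.0595). The risers were SAG101 (1.22, SE 0.15), EDS1 (0.79, SE 0.16), CBP60G (0.81, SE 0.21), SARD1 and PNP-A, while GRX480 fell (-0.55, SE 0.11). The Col-0 signal of SARD1 and PNP-A was not well above background on any array. On average over the arrays they were at least 1.65-fold and 1.66-fold higher, limits that equal the plain difference of the mean levels and carry no error. SARD1 had 0.18 on replicate 2 and 0.53 to 1.25 on the others. CBP60G and PNP-A were named after their values were seen. This list had a median of 0.94 on replicate 4 and of 0.08 to 0.20 on the others, and passed in 8 of 20 alternative settings. It passed without replicate 2 (median 0.68, adjusted p = 0.000240) but not without replicate 4 (median 0.12, adjusted p = 0.195).

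Heat shock genes were lower in the mutant: 0 of 12 rose, 11 fell and 1 did not pass, or 12 falling adjusted over the list alone (median -0.92, camera adjusted p = 3.30e-08, adjusted p = 0.560 with an estimated correlation). Besides HSP17.6C, HSP90.1 (-1.42, SE 0.11, n = 4) and the heat shock transcription factor HSFA2 (-1.36, SE 0.12) fell. HSP21, a chloroplast small heat shock protein, was not well above background in the mutant on any array. It was on average at least 3.01-fold lower (adjusted p = 0.000624). Flavonoid and anthocyanin genes were lower as well, with 0 of 14 rising, 9 falling and 5 not passing, or 11 falling adjusted over the list alone (median -0.65, camera adjusted p = 9.70e-06, adjusted p = 0.560 with an estimated correlation), and fry did not call them (adjusted p = 0.0656). The flavonol synthase FLS1 (-1.63, SE 0.16), the hydroxylase F3H (-1.56, SE 0.13), the chalcone synthase TT4 (-1.45, SE 0.11) and the regulator MYB12 (-0.65, SE 0.07) fell. All 5 measured genes of ER bodies, the endoplasmic reticulum compartments that store β-glucosidases, fell, and the same 5 adjusted over the list alone (median -0.70, camera adjusted p = 0.000562, adjusted p = 0.560 with an estimated correlation). They are BGLU21 (-1.13, SE 0.14), NAI1 (-0.84, SE 0.09), BGLU22 (-0.70, SE 0.09), NAI2 (-0.57, SE 0.09) and PYK10 (-0.50, SE 0.09), the last named after its value was seen.

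Cytosolic ribosomal protein genes were slightly lower: 1 of 170 rose, 38 fell and 131 did not pass, or 1 and 35 adjusted over the list alone (median -0.18, camera adjusted p = 3.30e-08, adjusted p = 0.560 with an estimated correlation). Their median was 0.03 with median centring, where that of all genes was 0.15, and fry did not call them (adjusted p = 0.0897). AT5G22440 (-1.02, SE 0.12, n = 4), AT2G20450 (-0.79, SE 0.08), AT3G58660 (-0.76, SE 0.08) and AT5G59850 (-0.63, SE 0.07) fell, and AT5G39800, named after its value was seen, rose (0.27, SE 0.07). Cell cycle genes were lower too, with 0 of 24 rising, 9 falling and 15 not passing, or 10 falling adjusted over the list alone (median -0.22, camera adjusted p = 0.000400, adjusted p = 0.560 with an estimated correlation). Those that fell include the replication genes PCNA1 (-0.62, SE 0.09), PRL (-0.40, SE 0.08), MCM2 (-0.36, SE 0.09) and PCNA2 (-0.32, SE 0.07). With median centring these 4 were -0.40, -0.12, -0.10 and -0.04 and did not pass (adjusted p = 0.605 to 0.987). MCM2 did not pass in 7 of 18 alternative settings.

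Iron deficiency genes were lower: of 10 measured, 1 rose, 7 fell and 2 did not pass, with 1 and 7 adjusted over the list alone (over the 9 with a value on every array, median -0.51, camera adjusted p = 0.00124, adjusted p = 0.560 with an estimated correlation). The nicotianamine synthase NAS4 (-1.17, SE 0.08, n = 4), the ferric reductase FRO2 (-0.81, SE 0.08) and the regulators bHLH38 (-0.68, SE 0.07) and bHLH39 (-0.51, SE 0.07) fell, while the iron store ferritin FER1, named after its value was seen, rose (0.70, SE 0.16). With the regulator BHLH100 at its bound the median was -0.50. Root tissue markers were lower, with 2 of 19 rising, 8 falling and 9 not passing, the same adjusted over the list alone (median -0.35, camera adjusted p = 0.00315, adjusted p = 0.560 with an estimated correlation). The vacuolar channel TIP2;3 (-1.11, SE 0.15), the endodermal regulator SCR (-0.54, SE 0.08) and THAS1 (-0.45, SE 0.07) fell, and MYB36 (0.47, SE 0.07) and WOX5 (0.37, SE 0.09, named after its value was seen) rose. SCR and THAS1 followed the dyes: they had -0.01 and -0.06 on replicate 1 and -0.17 and -0.18 on replicate 3, against -1.09 to -0.71 on replicates 2 and 4. Neither passed without the dye term (adjusted p = 0.0648 and 0.0521). The ER body gene PYK10 is a member of this list as well. Of 5 measured phosphate starvation genes, PAP17 (-0.97, SE 0.18), SPX1 (-0.56, SE 0.17) and SQD2 (-0.55, SE 0.07) fell, 0 rose and 2 did not pass, the same adjusted over the list alone (median -0.55, camera adjusted p = 0.0279, adjusted p = 0.560 with an estimated correlation). SPX1 had 0.11 on replicate 4 and did not pass in 10 of 18 alternative settings, among them the deposited value table (adjusted p = 0.0915) and trend and robust eBayes (adjusted p = 0.0532). The list's call was lost in 7 of 20 alternative settings, among them without replicate 2 (median -0.30, adjusted p = 0.0651) and without replicate 3 (median -0.56, adjusted p = 0.0511).

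Photosynthesis genes were higher in the fit, with 14 of 38 rising, 4 falling and 20 not passing, or 15 and 5 adjusted over the list alone (median 0.23, camera adjusted p = 0.0182, adjusted p = 0.701 with an estimated correlation). Their median followed the dyes: it was -0.44 and -0.26 on replicates 1 and 3, where the mutant carried Cy3, and 0.87 and 0.63 on replicates 2 and 4. The call was lost in 11 of 20 alternative settings, among them without replicate 2 (median 0.20, adjusted p = 0.226) and without replicate 3 (median 0.18, adjusted p = 0.0896). The chlorophyll-binding protein LHB1B1 rose in the fit (0.71, SE 0.09, n = 4) with positive ratios on 2 of the 4 arrays, PSAK (0.56, SE 0.07) with positive ratios on 3, and PSAE-1 (0.52, SE 0.07) with positive ratios on all 4. PSAK had -0.08 and 0.04 on replicates 1 and 3 against 1.15 and 1.11 on replicates 2 and 4. RCA, the activase of Rubisco, fell (-0.70, SE 0.09, with the Col-0 signal saturated on 1 array, where the size of the fall is a lower limit), as did PRK (-0.55, SE 0.11), GAPB (-0.38, SE 0.07) and RBCS1A (-0.33, SE 0.10), the last 3 named after their values were seen.

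**Figure D3:**
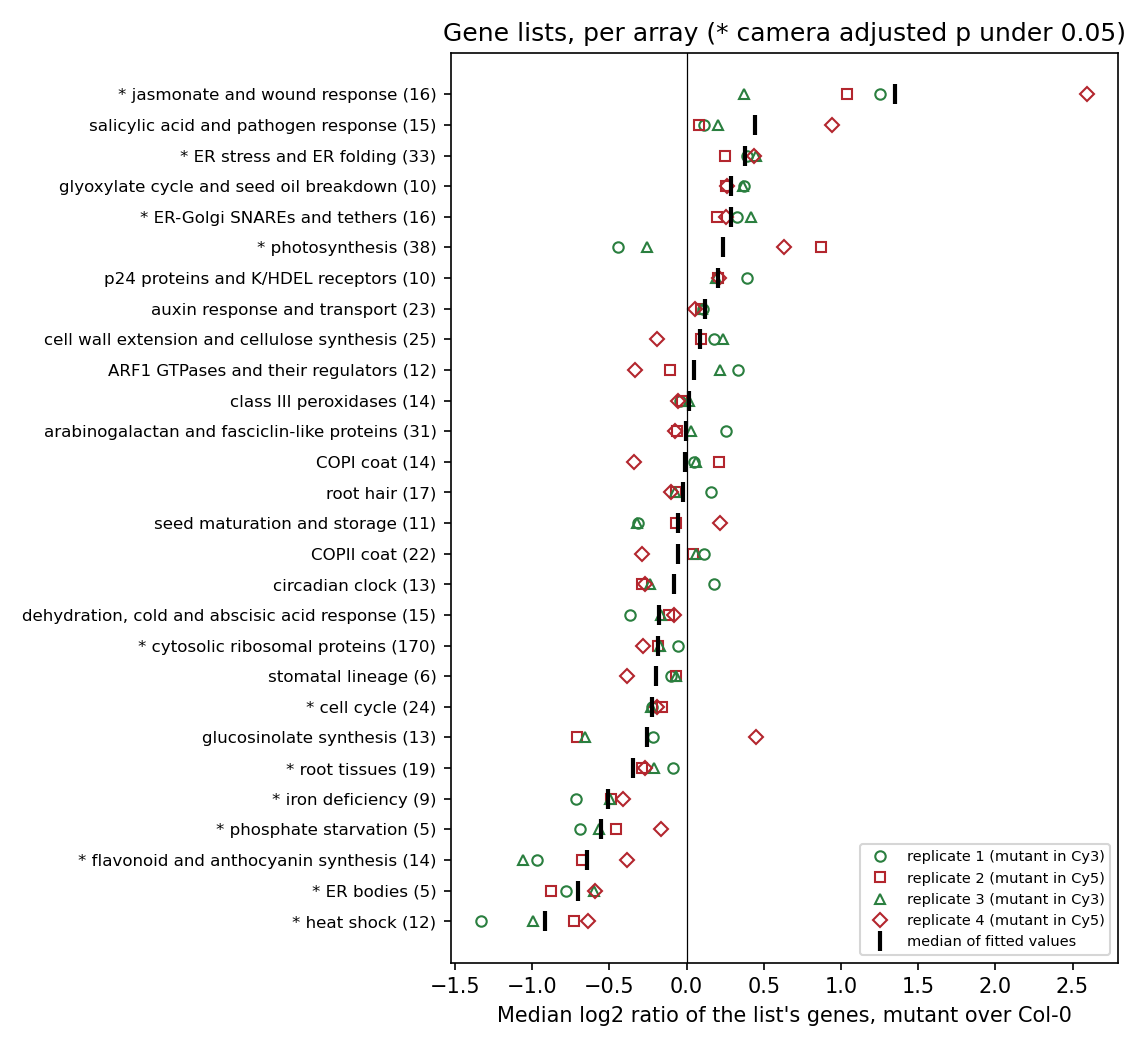
Median log2 ratio of mutant over Col-0 of the measured genes of each of the 28 lists on each of the 4 arrays (open symbols, coloured by the dye of the mutant) and over the fitted values (black bars), with the number of measured genes in brackets. Stars mark the 12 lists with a camera adjusted p under 0.05. Jasmonate genes lie between 0.37 and 2.60, heat shock genes between -1.33 and -0.64, and photosynthesis genes on both sides of 0 according to the dye.

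Among 13 circadian clock genes, 3 rose, 6 fell and 4 did not pass, or 4 and 6 adjusted over the list alone (median -0.08, camera adjusted p = 0.279). The morning genes RVE1 (-1.41, SE 0.15, n = 4), LHY (-1.41, SE 0.09) and CCA1 (-1.24, SE 0.09) fell, and the evening gene ELF3 (0.57, SE 0.07) rose, together with PCL1 (0.51, SE 0.08) and TOC1 (0.31, SE 0.08), the last 2 named after their values were seen. With median centring the list's median was 0.10, against 0.15 for all genes, and camera called it lower (adjusted p = 0.0229). The median was -0.26 without replicate 1 and 0.09 without replicate 3 and did not pass (adjusted p = 0.134 and 0.234). Of 10 genes of the glyoxylate cycle and seed oil breakdown, 5 rose, 1 fell and 4 did not pass, or 6 and 1 adjusted over the list alone (median 0.29, camera adjusted p = 0.0931, fry adjusted p = 0.0247, adjusted p = 0.560 with an estimated correlation). The lipase SDP1 (0.78, SE 0.10), CSY2 (0.55, SE 0.08), CSY3 (0.51, SE 0.08), PKT3 (0.42, SE 0.07) and PCK1 (0.33, SE 0.08) rose, and the isocitrate lyase ICL fell (-0.70, SE 0.12), PCK1 and ICL being named after their values were seen. The ratio of PKT3 was -0.00092 as the mean of its probes. Of 11 measured seed maturation and storage genes, 0 rose, 1 fell (the storage protein CRA1, -0.48, SE 0.11, well above background in the mutant on 2 arrays) and 10 did not pass, or 0 adjusted over the list alone (median -0.06, camera adjusted p = 0.262). This list passed without replicate 4 (median -0.15, adjusted p = 0.0260) and with median centring (median -0.12, adjusted p = 0.0295).

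Cell wall genes moved both ways: of 25, 8 rose, 4 fell and 13 did not pass, the same adjusted over the list alone (median 0.08, mean 0.25, camera adjusted p = 0.402). The xyloglucan endotransglucosylases XTH18 (2.37, SE 0.20, n = 4), XTH24 (1.69, SE 0.08) and XTH19 (1.31, SE 0.08) rose. The expansins EXPA5 (-1.20, SE 0.08), EXPA15 (-0.84, SE 0.11), EXPA8 (-0.61, SE 0.11) and EXPA10 (-0.53, SE 0.12) fell, the last 3 named after their values were seen. Median centring gave this list a median of 0.34 and a call (adjusted p = 0.0229). Its median was -0.01 without replicate 2 and 0.18 without replicate 4, without a call (adjusted p = 0.770 and 0.0521). Of 31 measured arabinogalactan and fasciclin-like proteins, 7 rose, 6 fell and 18 did not pass, the same adjusted over the list alone (median -0.00, camera adjusted p = 0.929), with AGP22 (-1.20, SE 0.10), AGP13 (-0.86, SE 0.09), AGP41 (-0.84, SE 0.09) and FLA8 (-0.74, SE 0.09) among those that fell. Of 23 auxin genes, 7 rose, 4 fell and 12 did not pass, the same adjusted over the list alone (median 0.12, camera adjusted p = 0.211). IAA2 (0.87, SE 0.09), IAA29 (0.80, SE 0.14), GH3.3 (0.67, SE 0.08) and DFL1 (0.58, SE 0.09) rose, and PIN4 (-0.37, SE 0.10), SAUR20 (-0.33, SE 0.08) and SAUR21 (-0.27, SE 0.08), named after their values were seen, were among those that fell.

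Of 14 class III peroxidases, AT3G32980 (0.56, SE 0.14, n = 4), AT2G38380 (0.41, SE 0.08) and AT3G21770 (0.26, SE 0.07) rose, AT3G01190 (-0.82, SE 0.09), AT5G17820 (-0.59, SE 0.07) and AT4G16270 (-0.35, SE 0.10) fell and 8 did not pass, the same adjusted over the list alone. AT3G21770 and AT4G16270 were named after their values were seen, and AT3G32980 did not pass in 6 of 18 alternative settings. AT3G01190 had -0.41 and -0.48 on replicates 1 and 3 against -0.99 and -1.41 on replicates 2 and 4. The median of this list was 0.02, its mean -0.05 and camera's direction lower (adjusted p = 0.701). Of 17 root hair genes, LRX2 (0.68, SE 0.13) and PRP1 (0.52, SE 0.09) rose, SHV2 (-0.58, SE 0.08) fell and 14 did not pass, the same adjusted over the list alone. The root hair median was -0.02, the mean 0.00 and camera's direction lower (adjusted p = 0.694). In the stomatal lineage, TMM (-0.47, SE 0.07), EPF2 (-0.42, SE 0.10) and SPCH (-0.34, SE 0.10) fell, 0 genes rose and 3 did not pass, the same adjusted over the list alone (median -0.20, camera adjusted p = 0.134). Of 15 measured dehydration, cold and abscisic acid genes, RD22 (0.41, SE 0.08) rose, KIN1 (-0.64, SE 0.14), LTI78 (-0.60, SE 0.11), KIN2 (-0.43, SE 0.13, named after its value was seen) and CBF2 (-0.41, SE 0.08) fell and 10 did not pass, or 1 and 5 adjusted over the list alone (median -0.18, camera adjusted p = 0.0753). It passed in 4 of 20 alternative settings: without replicate 4 (adjusted p = 0.0280) and with processed signals, the log ratio and the deposited value table (adjusted p = 0.0267 to 0.0271). Of 13 glucosinolate genes, the regulator MYB29 (-0.91, SE 0.19) and CYP79F1 (-0.86, SE 0.24) fell, 0 rose and 11 did not pass, or 1 falling adjusted over the list alone (median -0.26, camera adjusted p = 0.134). On replicate 4 MYB29 had 0.11 and CYP79F1 0.20, and they did not pass in 5 and 8 of 18 alternative settings. The list's median was 0.45 on replicate 4 and -0.71 to -0.22 on the others, and it passed without replicate 1 (median -0.35, adjusted p = 0.0279), without replicate 4 (median -0.56, adjusted p = 0.000220), and with median centring (median 0.00, adjusted p = 0.0229). It did not pass without replicate 2 (median 0.04, adjusted p = 0.861) or without replicate 3 (median -0.13, adjusted p = 0.372).

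Camera called 12 of the 28 lists and fry 9, of which 7 were shared. With an estimated correlation 0 lists passed, 0 also at an unadjusted p under 0.05, and the lowest p was 0.0604. The adjusted p of 0.560 in that test is a value shared by lists with an unadjusted p of 0.0604 to 0.220. It therefore does not tell those lists apart. The dye effect, tested in the same limma fit, was called for 0 genes, and 1796 had an unadjusted p under 0.05. Without replicate 2 the dye effect was called for 2752 genes and without replicate 4 for 36. Without the dye term 8 named genes did not pass: ARFA1E, STL2P, SEC24C, LHB1B1, PSAK, THAS1, SCR and CRA1.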

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

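The test of a general stretch of replicate 4 was chosen after its result had been seen. The labels give no group that sets 1 array apart, so no biological explanation was tested for either of the patterns weighed here.

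Replicate 4 correlated least with the mean of the other arrays, with r = 0.676 across genes (genes are not independent replicates) against 0.799 to 0.870 for replicates 1 to 3. It also stood apart in its red median net signal of 57 (114 to 122 on the others) and in its 36 saturated green spots (0 to 2 on the others). A dim red channel would let the correlation recover among bright genes. Over the 5002 genes brightest in that channel, the gap to the lowest of the other arrays was 0.136 (bootstrap SE 0.00886), against 0.123 over all genes, which argues against dimness as the whole cause. A difference of the plate or of the seedlings of that replicate stays open and was not tested.

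Jasmonate genes rose most on replicate 4, where their median of 2.60 was 3.02 times the 0.86 of the mean of the other arrays. If all ratios of that array were stretched, other changed genes would show the same steepness. Over 6402 changed genes outside the list, the slope of replicate 4 on the mean of the others was 1.01 (SE 0.00829). This argues against a general stretch among those genes. They were called in a fit that includes replicate 4, so the slope does not cover genes on which that array stood too far apart. Over all genes its ratios spread most (SD 0.553, against 0.399 to 0.459 on the others). A stronger jasmonate or wound response in the mutant seedlings of that replicate, or a weaker one in its Col-0 seedlings, stays open and was not tested.

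Of 122 named genes, 7 had 1 array far from the other 3, of 28 lists 5, and of 6 array measures 2, where chance gives about 1 in 20. On replicate 4 these were TAT3 at 6.73 (2.78 to 3.07 on the others), AT2G27420 at -2.15 (-3.69 to -3.46), RVE1 at -0.67 (-1.72 to -1.58), BGLU22 at -1.06 (-0.63 to -0.54) and SAG101 at 1.88 (0.93 to 1.06). MEMB11 had 0.36 on replicate 1 (0.69 to 0.73), and MYB12 had -0.73 on replicate 3 (-0.63 to -0.62). Among list medians, salicylic acid and pathogen genes had 0.94 (0.08 to 0.20) and stomatal lineage genes -0.38 (-0.10 to -0.07) on replicate 4. On replicate 1, p24 proteins and K/HDEL receptors had a median of 0.39 (0.19 to 0.21), circadian clock genes 0.18 (-0.29 to -0.24) and root hair genes 0.16 (-0.10 to -0.07).

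Probes left out of the gene fit were those paired with no locus and those second to a probe named by accession. When they were added, 531 of the 2776 tested (19.1%) changed, 307 higher and 224 lower in the mutant, with log2 ratios from -2.85 to 2.57. What the probes with no locus measure is not known.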

How the results depend on the processing

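Some alternatives were chosen after the data were seen. They added the probes left out of the gene fit, or used the background flags as named in the files. They also took only genes of small dye effect, or kept the left-out list entries. The slide as a block was not run, since all arrays share 1 slide. Changed genes stayed within 1.5 times of 6413 in the settings other than those named here. Leaving out 1 array gave 914 to 9968 changed genes, 511 to 5498 higher, 371 to 4470 lower, 448 to 730 changed by at least 2-fold and 0 to 2752 with a dye effect. With 1 array left out, 1 of the dye orders rests on 1 array. Median centring gave 876 changed, 752 higher and 124 lower genes, of which 865 were among the 6413. Genes changed by at least 2-fold numbered 1297 with processed signals and loess, 1303 with Agilent's log ratio and 1306 with the deposited value table, against 587, and the cause was not tested. α2-COP kept its direction and its call in all settings, from -3.91 with processed signals to -1.12 as the mean of its probes. Lists called by camera ranged from 10 to 16 of 28 over the other settings, and the cause was not tested. Under an estimated correlation 0 were called. Lists with a negative estimate lost their calls too, so correlation between genes is not the whole cause of that loss.

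Of the 121 other named genes, 43 stayed on their side of the threshold with the same sign in every setting that tested them. Some were not tested in every setting. Of the 18 alternatives, SEC31A and HSP21 were tested in 16, and MRD1 and LOX2 in 17. Most losses came with median centring (65 genes), without replicate 1 (61) and without replicate 3 (61). With the dye effect fitted, the spread of a gene comes only from arrays that share a dye order. Without replicate 1 or 3 it rests on replicates 2 and 4 alone (r = 0.633 across genes). Without replicate 2 or 4 it rests on replicates 1 and 3 (r = 0.876). The cause of the losses with median centring was not tested. The signs that turned did so at values near 0 in the alternative settings. In the main fit α1-COP lay near 0, but SEC31B had -0.28 and PKT3 was among the genes that rose. α1-COP had -0.025 with processed signals, -0.021 with the log ratio, -0.020 with the value table, -0.0031 without replicate 1 and -0.096 without replicate 2, and kept its sign without replicate 3 or 4 (up to 0.10). SEC31B had 0.0027 with median centring and PKT3 -0.00092 as the mean of its probes. As the mean of their probes 11 further named genes kept their sign but lost their calls. Among them were GOS11 (0.29, limma adjusted p = 0.129), NAI2 (-0.28, adjusted p = 0.122) and KIN1 (-0.32, adjusted p = 0.0558). Of the lists, camera's direction turned for arabinogalactan proteins without background correction (median 0.0053), with processed signals (-0.022), the log ratio (-0.0121), the value table (-0.0120) and without replicate 3 (0.049). For COPII genes it turned without a dye term (median -0.0571), without background correction (-0.0618), with processed signals (-0.0575), the log ratio (-0.0540), the value table (-0.0535), median centring (0.18), the mean of probes (-0.0571), without replicate 3 (-0.061), without replicate 4 (0.012) and under fry (-0.0571). It turned for ARF1 genes without replicate 2 (0.022), for COPI genes without replicate 4 (0.11) and for root hair genes without replicate 3 (-0.036). The direction was kept with each of the other arrays left out, and over all 4 left-out arrays the median was 0.0060 to 0.051 for arabinogalactan proteins, -0.091 to 0.012 for COPII, 0.022 to 0.084 for ARF1, -0.12 to 0.11 for COPI and -0.092 to -0.030 for root hair genes. None of these lists passed camera in any setting.

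Of the 3 balanced assignments of the array signs, 1, the real one, called 6413 genes in limma, and the highest other called 0 (25 at an unadjusted p under 0.05). With 3 assignments the share cannot fall under 0.05. The median red signal of 57 to 122 over background limits what dim genes can show, and 73 tested genes have only a bound in the mutant and 44 in Col-0.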

Other observations

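The gene sets in this part were drawn up after the largest changes had been seen, and each test was fixed before the values of its members were looked at, except that ELIP2, whose value had been seen, was taken out of the light and UV-B set after a first run that included it; that run had met its prediction, and the run without ELIP2 did not decide it. All of them are hypotheses found and tested on the same 4 arrays.

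Genes that respond to sugar starvation or darkness were among the largest rises outside the fixed lists: ASN1 (2.45, SE 0.14, n = 4), SEN1 (2.38, SE 0.25), DRM2 (2.198, SE 0.27) and STP1 (2.18, SE 0.20). A low sugar supply in the mutant seedlings was put to 14 further genes of this response that had not been looked at, 13 of them measured. All 13 rose, with a median of 1.18, among them the amino acid catabolism gene BCAT2 (2.15, SE 0.18), DRM1 (1.54, SE 0.21), DIN10 (1.47, SE 0.22) and BGAL4 (1.25, SE 0.15). The median is above the 0.5 set in advance, and camera gave p = 7.28e-08, fry p = 0.0120 and camera with an estimated correlation p = 0.123. The response may therefore extend through this gene set, while whether sugar, darkness, growth or age of the seedlings is behind it was not tested.

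Morning clock genes were lower in the mutant. If the genotypes differed in clock time, genes of dawn should lie below genes of the evening. Of 9 dawn genes outside the fixed list, 7 fell, among them LNK2 (-1.23, SE 0.11), CDF1 (-1.12, SE 0.12) and RVE2 (-1.09, SE 0.07), with a median of -0.75. Of 4 measured evening genes CHE (0.34, SE 0.08) and JMJD5 (0.30, SE 0.07) rose, with a median of 0.23. The medians differed by 0.98 (two-sided exact permutation over 715 arrangements of the genes, p = 0.0140), which is consistent with a difference in clock time. The permutation takes the genes as independent, which clock genes are not, and the dawn genes alone had camera p = 1.32e-05, fry p = 0.00298 and p = 0.0503 with an estimated correlation. Harvest at different times and a changed clock in the mutant both predict it, and the labels give no time of harvest.

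MRD1 was the largest fall, and a missing segment around it in 1 of the lines might lower its neighbours too. The 5 tested genes on each side had a median of 0.059 (SE 0.23), which argues against a segment that spans all 10. Of the 10, 5 changed, and 3 of them, among them the nearest on either side, fell by 0.37 to 0.42, far less than MRD1 (-3.42). The others that changed rose, AT1G53440 by 1.44 and AT1G53430 by 0.47. MRD1 itself was well above background in the mutant on 3 of the 4 arrays, which argues against a shorter segment that removes it. Cross-hybridisation of its probe was not tested, so a loss of MRD1 alone is not settled. Linkage to the α2-COP locus was tested as well. MRD1 lies on chromosome 1 and α2-COP on chromosome 2, which argues against linkage as the cause of its fall, and 42.5% of the 20 tested genes on each side of α2-COP changed, against 32.0% of all genes.

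The light-induced gene ELIP1 was among the 12 largest falls, and flavonoid genes were lower as a group, with ratios down to -1.63. A lower response to light or UV-B could account for both. The 8 measured genes of this response not looked at before had a median of -0.45, between the -0.5 that would have spoken for it and the -0.25 that would have spoken against it. Of these, 5 fell, among them HYH (-1.30, SE 0.09) and UGT84A1 (-0.90, SE 0.15), 2 rose, RUP1 (0.46, SE 0.08) and UVR3 (0.43, SE 0.08), and WAKL8 did not pass. Camera gave p = 0.0549, fry p = 0.0199 and camera with an estimated correlation p = 0.266. The set passed in 7 of 20 alternative settings, fry among them, with the lowest p of 0.00958 under median centring, where the median was -0.30, and the medians of all settings lay between -0.57 and -0.30, so the test leaves the question open.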
